A study of Mus musculus with 4 samples.

How the data were processed

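Whole genome bisulfite sequencing was measured in 4 libraries of sorted mouse spleen B cells, 2 from the Dfl group and 2 from the DKO group. Bisulfite turns unmethylated cytosine into a base that is read as T, and leaves both 5-methylcytosine and 5-hydroxymethylcytosine reading as C, so a methylation level here is the sum of both marks. Per the labels' protocols, unmethylated lambda phage DNA was added before conversion, conversion took 4 hours, and 150 bp paired-end reads were made.

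The deposited values are counts: per the file headers, each CpG has for each library a count of reads that read C and a count of reads that read C or T. The submitters' processing notes name BSMAP 2.90 and Picard and the mouse builds mm10 and GRCm38, with no role or order, and how reads were filtered or counted is not given in the sources used here. The table held 21909677 CpG positions, no C count above its total, and no 2 neighbouring positions, so each CpG is listed once. Whether reads of both strands were summed is not given. The highest total was 65535, held by 41 positions, so true totals there are unknown. PCR duplicates cannot be told from independent molecules in counts. Reads of a stretch are sums over its CpGs, so a read that crosses several CpGs is counted at each. Intervals from read counts therefore cover counting error alone and are too narrow.

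CpGs on the autosomes and X with at least 5 reads in each of the 4 libraries were kept, 6500277 or 30.4% of those listed. Reads were summed over promoter regions, gene bodies and CpG clusters with at least 5 kept CpGs, 1 kb windows with at least 4 and 100 kb windows with at least 100. The level of a region is its C reads as a percent of its reads, and a difference is the DKO mean minus the Dfl mean in percentage points. Gene positions came from a RefSeq table of GRCm38.p6, the same build. That table has no strand and no exons, and no genome sequence was used, so the design fixed earlier could not be followed at 3 points. The promoter region is 1 kb either side of whichever gene end has more CpG positions, a stand-in for the start, with 609 ties going to the lower coordinate. The gene body runs from 1 kb inside that end to the other end, or over the whole gene for Igh constant genes. Where the wrong end was chosen, the body therefore holds the true start. CpG islands are replaced by clusters of at least 25 CpG positions in 500 bp, merged, as foreseen. Exons, introns and G-quadruplex motifs were not analysed here. Among 8403 genes with both ends measured, the chosen end was the less methylated one in 81.5%, at a median of 32.0% against 88.0% at the other end. For Cd19 the chosen end was at 91.5% and the other at 22.5% in Dfl, so the chosen end is doubtful there and the body may hold the start.

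Regions were tested with the quasi-likelihood test of edgeR 4.0.16 in R 4.3.3 on C and T counts, with 1 coefficient per library for coverage and the group effect on the log ratio. A call needed a Benjamini-Hochberg adjusted p under 0.05 and a difference of at least 10 points, with no minimum for 100 kb windows. Adjustment ran over protein-coding genes, so genes of other types, such as the Igh constant genes, have no adjusted p over all genes. Gene lists, 18 with 283 genes, were tested with camera at a preset correlation of 0.01 and at an estimated one, and with fry, in limma 3.58.1 on log2 of C plus 2 over T plus 2. Lists needed 3 measured members. Single values used a two-sided exact permutation test, for which 2 against 2 cannot go below p = 0.333. Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 did the rest.

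The edgeR test was tested on simulated counts with 200 changed regions per kind, 100 for each size of change. It recovered 18% of 15-point and 58% of 30-point changes at promoter regions (14299 simulated), 86% and 100% at gene bodies (17829), 23% and 69% at CpG clusters (16191), 1% and 31% at 1 kb windows (60000), and 100% of both at 100 kb windows (24064). Missing calls at promoter regions and 1 kb windows therefore exclude little.

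With 1 library left out, the lone sample of its group is assumed to vary like the other group. That assumption is doubtful, since the dispersion was lower without a DKO library than without a Dfl library at every kind of region. At CpG clusters it was 0.0239 and 0.0238 without DKO replicates 1 and 2, against 0.0564 and 0.0562 without Dfl replicates 1 and 2. Counts of calls with different libraries left out are therefore not directly comparable. Groups, tests, gene lists, alternatives and the rule for named genes were fixed before the data were examined. The rule takes the 12 largest differences each way among called promoter regions with both DKO libraries on the same side of both Dfl libraries, 6 each way for gene bodies and for 1 kb windows, every list member called, and Tet1, Tet2, Tet3, Cd19, Pax5, Aicda, Myc, Bcl6 and the Igh constant genes. Alternatives were at least 10 reads or at least 1 read per CpG, the top 0.5% of coverage left out, autosomes only, limma, the replicate number as a block, centring on the genome-wide change, no minimum difference or 20 points (2 for 100 kb windows), at least 10 CpGs (300 per 100 kb window), promoter regions from 2 kb upstream to 500 bp downstream, windows of 500 bp or 5 kb, an unweighted mean, level classes from 1 Dfl library, and leaving out each library. The other end of each gene, and chromosome 15 left out, were added after seeing the data. Relative coverage, used for deletions and chromosomes, is the mean coverage of a stretch over that of the median autosome, without CpGs summing to over 81 reads except inside Tet2 and Tet3. Deleted segments are the longest run of 500 bp bins with mean DKO coverage under 0.25 of Dfl.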

Results

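DNA methylation was measured across the genome of spleen B cells from C57BL/6J mice 10 weeks old. The DKO group (n = 2) holds B cells in which a Cre driven by Cd19 deleted Tet2 and Tet3, sorted by a YFP reporter, and the Dfl group (n = 2) holds control B cells sorted as CD19-positive and YFP-negative. Tet2 and Tet3 oxidise 5-methylcytosine, the first step of its removal. Reads over CpGs totalled 186712592 and 128244377 in Dfl replicates 1 and 2, and 304422831 and 180040513 in DKO replicates 1 and 2, with median coverage of 7, 4, 11 and 6 reads per CpG. Unconverted reads on lambda made up 0.245% (95% Wilson interval 0.239 to 0.251) and 0.242% (0.236 to 0.249) in Dfl, and 0.222% (0.218 to 0.226) and 0.293% (0.288 to 0.298) in DKO. The labels do not say whether replicates came from separate animals, so p-values measure only the spread between these samples.

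The targeted genes were examined first, since a deleted segment loses its reads. Reads are summed over the CpGs of a segment and are not all independent, so the Poisson intervals below are too narrow. In Tet2 (chromosome 3, 133463677 to 133545136) coverage between 133468884 and 133472676 fell to 2.91% of the Dfl mean in DKO replicate 1 (95% Poisson interval 1.502 to 5.08, 12 reads) and 6.34% in DKO replicate 2 (3.55 to 10.5, 15 reads), against 252 and 156 reads in Dfl. In Tet3 (chromosome 6, 83362373 to 83457208) coverage between 83402148 and 83405337 was 3.90% of Dfl in DKO replicate 1 (2.53 to 5.76, 25 reads) and 3.55% in DKO replicate 2 (1.89 to 6.06, 13 reads), against 432 and 215 reads in Dfl. Coverage of the rest of Tet2 was 1.01 and 1.06 times Dfl, and of the rest of Tet3 0.997 and 1.05 times. Both libraries labelled DKO had lost these segments and both Dfl libraries had them. The segments were picked from the DKO coverage itself, so the remaining percentages are biased low. Past the end of the Tet2 segment, bins from 133472677 to 133474176 were still lower in both DKO libraries than in both Dfl libraries. Between 133473177 and 133473676 relative coverage was 0.0424 and 0.222 in DKO, against 0.785 and 0.871 in Dfl. The deletion may therefore run beyond the segment. Leaving out Dfl replicate 1 or Dfl replicate 2 moved the mean Tet3 percentage from 3.73 to 4.31 or 3.28. Outside these genes, DKO replicate 2 had 1.30 times the Dfl coverage of chromosome 15 and 0.399 times that of Y, while its other autosomes lay between 0.990 and 1.01.

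**Figure D1:**
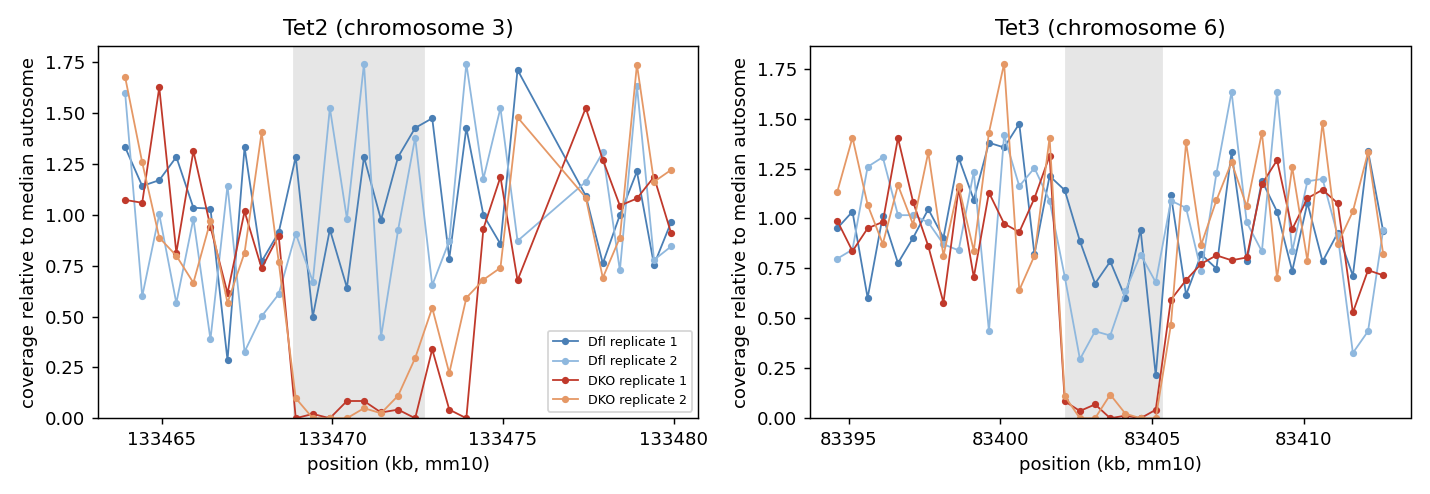
Coverage in 500 bp bins around the deleted segments of Tet2 and Tet3, relative to the median autosome, with 1 line per library and the segment shaded. Averaged over a segment, the DKO libraries lie between 0.0237 and 0.0584 and the Dfl libraries between 0.578 and 0.946.

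Over all kept CpGs, B cells without Tet2 and Tet3 had less methylation, not more. The level was 80.4% ± 0.240 (SD, n = 2) in Dfl and 75.8% ± 0.308 (SD, n = 2) in DKO, a difference of -4.59 points with both DKO libraries below both Dfl libraries (exact permutation test, two-sided p = 0.333, the smallest possible here). CpGs with few neighbours lost most: those with 1 to 2 CpGs within 250 bp, counting the CpG itself, went from 81.8% ± 0.332 to 71.2% ± 0.354, and those with 3 to 5 from 83.3% ± 0.371 to 76.4% ± 0.175. Where 25 or more CpGs lay together the level was 37.6% ± 0.0972 in Dfl and 38.8% ± 0.756 in DKO. By position, intergenic CpGs differed by -5.24 points, gene bodies outside promoter regions and clusters by -3.76, flanks of CpG clusters by -1.82, CpG clusters by 0.915 and promoter regions by 0.5999. Autosomes together differed by -4.56 points, chromosome 9 by -1.73 and chromosome 3 by -6.45, and X by -6.71. Each of these classes had an exact permutation p of 0.333, two-sided. With at least 10 reads per CpG the signs of CpG clusters (-0.358), promoter regions (-2.03) and the densest CpGs (-0.192) turned, and gene bodies (-5.80) and flanks of CpG clusters (-4.05) differed more than intergenic CpGs (-2.41).

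**Figure D2:**
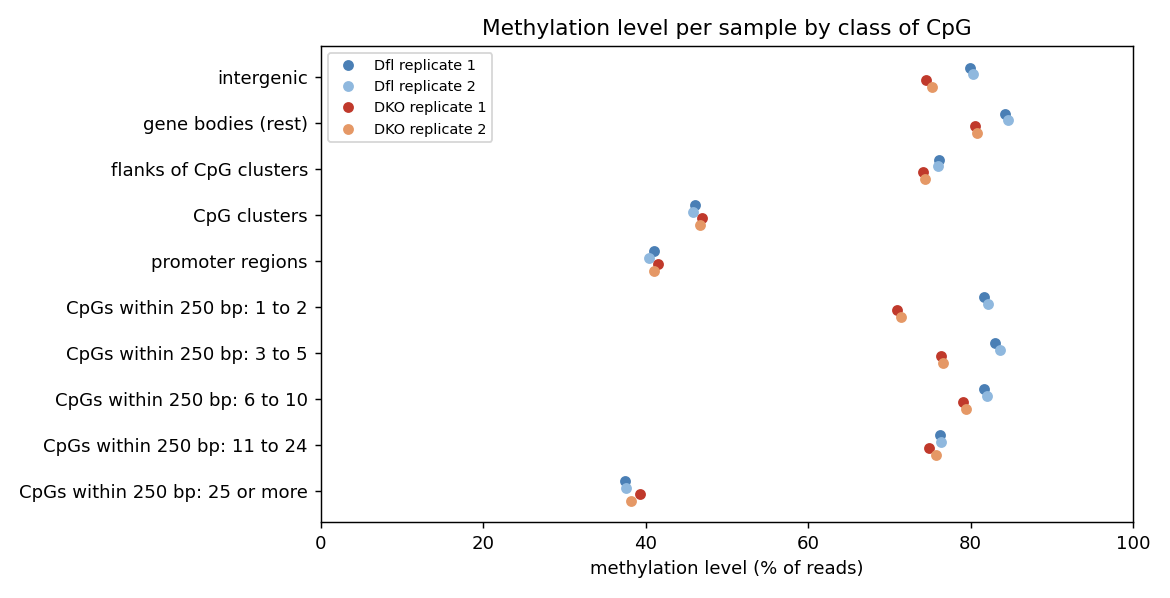
Methylation level (percent of reads that read C) of each library by class of CpG, 1 point per library. DKO points lie left of Dfl for sparse CpGs, 71.2% against 81.8% on average, and close to Dfl in CpG clusters, 46.8% against 45.9%.

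Windows of 1 kb with low methylation were higher in DKO on average. Classed by the mean of the 4 libraries, windows at 0 to 20% differed by 2.47 points, at 20 to 40% by 5.25, and at 80 to 100% by -3.50. When they were classed by Dfl replicate 1 and compared with Dfl replicate 2, windows at 0 to 20% were at 8.32% in that library and at 13.5% and 13.98% in the DKO libraries, and windows at 20 to 40% at 32.4% against 39.6% and 40.4%. Windows at 80 to 100% were at 89.3% against 84.4% and 84.3%. The class means have no test of their own. Classing by Dfl replicate 2 gave differences of 5.36, 7.56 and -4.79 points for the same classes.

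Loss of methylation covered long stretches of gene-poor DNA. Of 24064 windows of 100 kb, edgeR called 16894 lower and 1443 higher in DKO at an adjusted p under 0.05, with a median difference of -6.90 points. Of 8432 windows without a protein-coding gene, 92.4% were lower and 1.34% higher, with a median level of 82.3% and 82.8% in Dfl and 72.5% and 72.8% in DKO. Of 1912 windows with 4 or more genes, 29.2% were lower and 9.00% higher, with a median difference of -0.553 points. Windows in the lowest quartile of CpG count differed by a median of -11.1 points, and those in the highest by -1.11. Relative to the genome-wide change, 5906 windows were higher and 11733 lower. A minimum of 10 reads per CpG left only 108 windows to test. Without Dfl replicate 1 the higher calls numbered 836, and with at least 10 reads per CpG 2 were higher and 85 lower.

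**Figure D3:**
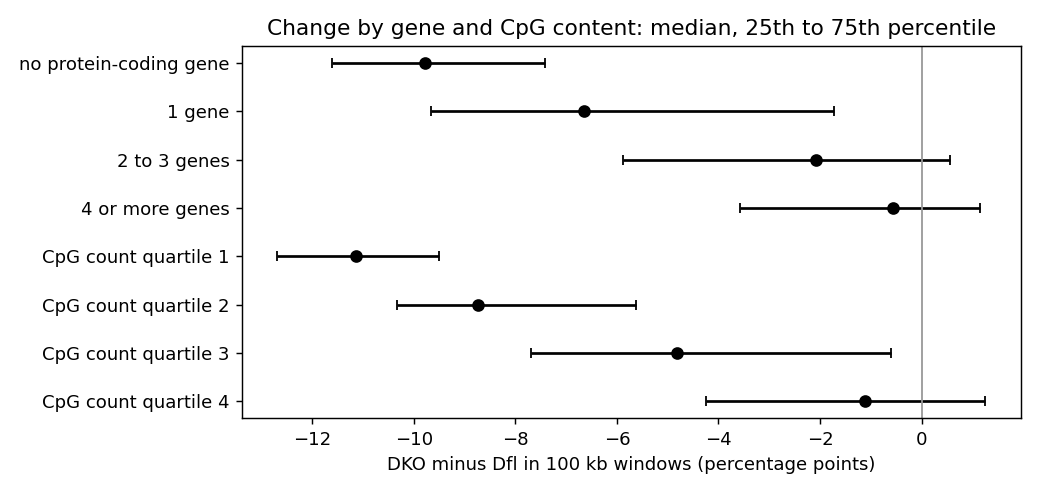
Difference in methylation of 100 kb windows, DKO minus Dfl in percentage points, by number of protein-coding genes and by quartile of CpG count; points are medians and bars span the 25th to the 75th percentile. The median moves from -9.79 points without genes to -0.553 with 4 or more.

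Gene bodies went both ways. Of 17819, edgeR called 1235 lower and 256 higher in DKO by at least 10 points. Strand was not known, so a body may hold the start of its gene, and in short bodies a change may lie there. Among the largest gains were the body of Igll1, a part of the pre-B cell receptor (chromosome 16, 16861671 to 16863985), from 15.1% ± 9.75 to 59.7% ± 2.499 (SD, n = 2; edgeR adjusted p = 0.000307), that of the cytokine gene Clcf1 (chromosome 19, 4215238 to 4223505), from 27.6% ± 0.515 to 69.5% ± 5.53 (edgeR adjusted p = 9.18e-06), and that of the activation-induced transcription factor Egr3 (chromosome 14, 70078317 to 70082613), from 35.5% ± 0.876 to 72.0% ± 5.87 (edgeR adjusted p = 0.000123). Lrrc25 rose by 38.8 points, Amigo2 by 38.8 and H2aj by 36.5. The largest loss was in Klf2, which keeps B cells quiescent and guides their migration (chromosome 8, 72320062 to 72321654), from 68.7% ± 14.3 to 27.4% ± 7.08 on 5 CpGs with 29 to 58 reads per library (edgeR adjusted p = 0.00372). Ctsj fell by 38.4 points, Nrk by 37.8, Muc3a by 34.8, Tcl1b1 by 34.7 and Spink14 by 31.8, each on 5 to 8 CpGs. Relative to the genome-wide change, 1104 bodies were higher and 171 lower, and without DKO replicate 2 the higher calls numbered 417. Of 44 named regions called, 30 were still called without Dfl replicate 1, 28 without Dfl replicate 2, 24 without DKO replicate 1 and 32 without DKO replicate 2.

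The bodies of genes that define B cells were compared as lists. Of 19 measured B cell transcription factors, 13 rose and 1 (Klf2) fell at an edgeR adjusted p under 0.05, and 13 and 1 when adjusted over the list alone. With the 10-point minimum, 1 rose (Irf8) and 1 fell, over all genes and adjusted over the list alone. The Irf8 body (chromosome 8, 120737358 to 120756694) went from 56.9% ± 7.22 to 74.5% ± 0.651 (SD, n = 2), Bcl11a from 66.7% to 75.1%, Ikzf3 from 73.5% to 80.8%, and Pax5, which sets B cell identity, from 79.4% ± 0.0733 to 83.0% ± 0.118. Of 23 B cell receptor and surface genes, 10 rose and none fell, and adjusted over the list alone 10 rose and 1 fell. At 10 points these were 2, Cxcr5, a follicle homing receptor (12.1 points), and Vpreb3 (11.2 points), and 2 over the list alone. Camera found both lists higher than other genes (adjusted p = 1.02e-05 and 0.000145). Neither camera call held with an estimated correlation (adjusted p = 0.440 for both). The estimates, -0.00707 and 0.00675, lay below the preset 0.01, so a higher correlation did not end these calls. With so few libraries that setting has few degrees of freedom and called no list at gene bodies, so its losses decide little. Fry gave adjusted p = 0.00701 for the transcription factors and 0.0515 for the receptor genes. The fry call of the transcription factors was lost without Dfl replicate 1 (adjusted p = 0.343), Dfl replicate 2 (0.260), DKO replicate 1 (0.0775) or DKO replicate 2 (0.0588), and with at least 1 read (0.0665) or 10 reads (0.170).

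Of 22 measured bodies of lymphoma oncogenes and tumour suppressors, 13 rose and none fell, 14 rose adjusted over the list alone, and 5 rose by at least 10 points (6 over the list alone). Those 5 were the tumour suppressors Cdkn2b (chromosome 4, 89306289 to 89310032), from 15.8% ± 0.485 to 43.3% ± 0.668 (SD, n = 2), and Cdkn2a, from 20.5% ± 0.393 to 40.3% ± 1.19, and the oncogenes Myc, from 23.2% ± 4.15 to 41.4% ± 1.04, Pim1, from 9.59% ± 0.520 to 24.3% ± 3.88, and Mycn, from 6.66% ± 3.85 to 19.4% ± 13.8, the latter from 29.2% and 9.68%. With CpGs of at least 1 read the Myc body differed by -0.612 points. Camera placed the list above other genes (adjusted p = 2.12e-06), a call lost with an estimated correlation (adjusted p = 0.507) and with at least 10 reads (adjusted p = 0.0588). Fry gave an adjusted p of 0.0515.

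Camera called none of the other fixed lists at gene bodies with CpGs of at least 5 reads in all 4 libraries, the lowest adjusted p being 0.0624 (0.507 with an estimated correlation). Of 14 germline genes 5 fell, among them Syce1 by 20.1 points and Asz1 by 11.1, and fry found the list lower (adjusted p = 0.00701). That fry call was lost without Dfl replicate 1 (adjusted p = 0.343), Dfl replicate 2 (0.260) or DKO replicate 1 (0.175), and with at least 1 read (0.0765) or 10 reads (0.266). Of 11 plasma cell genes 3 rose, including Tnfrsf17, the receptor BCMA, by 14.7 points, and Mzb1 fell by 6.38. Of 12 germinal centre genes 2 rose. Of 14 DNA methylation enzymes 3 rose, Idh2, Dnmt3a and Tet3. Of 19 R-loop and G-quadruplex factors 1 rose (Rnaseh2b), and of 18 DNA damage response genes 1 rose (Xrcc6). In the list of T cell markers, Themis fell by 14.5 points and Cd2, which is not exclusive to T cells, rose by 12.2. The NK cell genes Eomes and Klrk1 fell by 12.5 and 10.2 and Tbx21 rose by 7.19. Falls were seen in 1 of 7 myeloid (Csf3r), 1 of 4 erythroid (Gypa) and 2 of 10 progenitor genes (Mecom, Rag1). Of 17 imprinted genes 3 fell and 1 rose. At this threshold, without a minimum difference, 3771 of all 17819 bodies fell and 1243 rose. The falls in myeloid, erythroid, progenitor and imprinted genes lie near that share. Of 24 developmental CpG island genes 1 fell, and of 13 housekeeping genes 1 rose. Adjusted over the list alone, the bodies higher and lower were 0 and 5 for germline genes, 3 and 1 for plasma cell, 1 and 0 for germinal centre, 3 and 0 for DNA methylation enzymes, 0 and 0 for R-loop factors, 1 and 0 for DNA damage response, 1 and 1 for T cell, 1 and 3 for NK cell, 0 and 1 for myeloid, 0 and 1 for erythroid, 0 and 2 for progenitor, 1 and 5 for imprinted, 0 and 1 for developmental and 0 and 0 for housekeeping genes. Camera did call some with 1 library left out: germinal centre genes without Dfl replicate 2 (adjusted p = 0.0202) or DKO replicate 2 (0.0155), R-loop factors without DKO replicate 2 (0.0161), T cell genes without Dfl replicate 2 (0.0478) or DKO replicate 1 (0.00183), and germline genes without Dfl replicate 2 (0.0478). With an estimated correlation none of these camera calls held. With a library left out that setting has too few degrees of freedom to be likely to call any list, so this decides nothing. Camera also called germinal centre (adjusted p = 0.0348), DNA methylation enzyme (0.00983) and R-loop genes (0.0483) with at least 1 read. It called these 3 and germline genes (0.0446 each) without the top coverage. None of these held with an estimated correlation (adjusted p from 0.484 to 0.558). Fry called the DNA methylation enzymes without DKO replicate 2 (adjusted p = 0.0359). Signs differed within some lists: the myeloid bodies had a median of 1.04 points and a mean of -0.454, and progenitor and developmental bodies had negative medians (-1.26 and -1.09) where camera's direction, relative to other genes, was up. Of the fixed genes, Tet1 differed by -1.42 points, Tet2 by -0.203, Bcl6 by -0.437, Aicda by 3.47 and Cd19 by 8.39, none past the test.

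**Figure D4:**
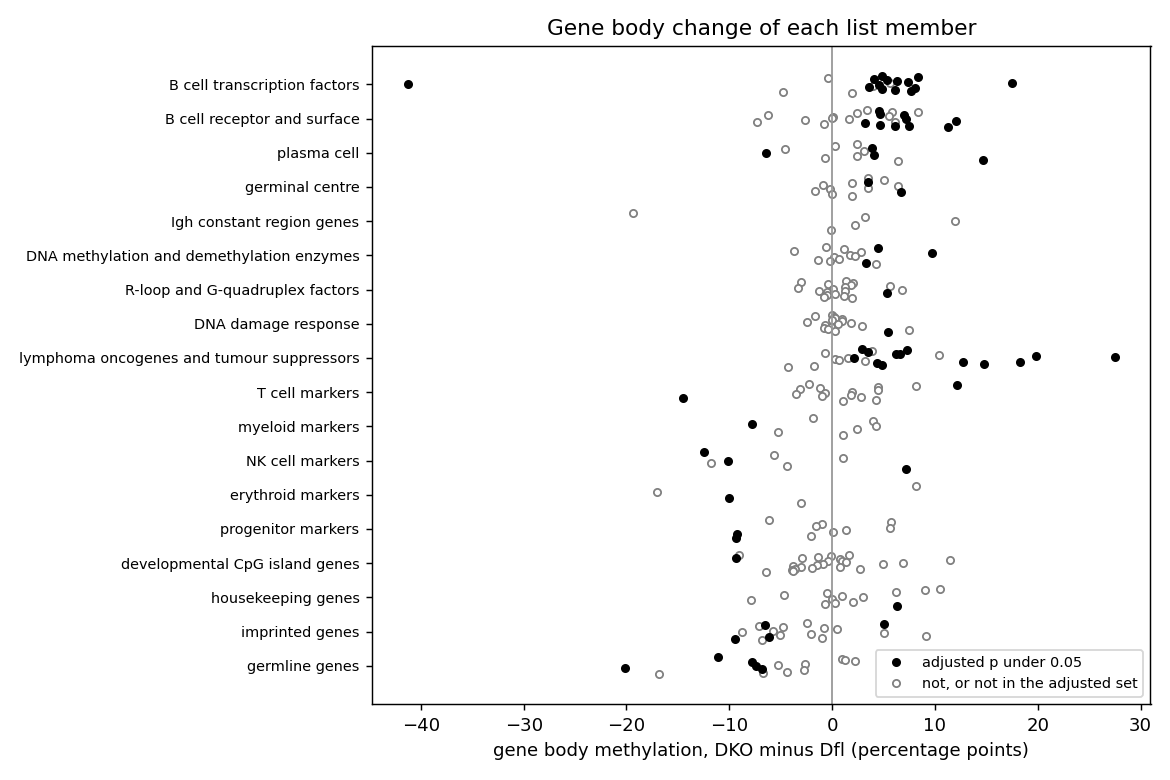
Gene body difference of each member of 18 gene lists fixed in advance, DKO minus Dfl in percentage points; filled points have an edgeR adjusted p under 0.05. Filled points of the B cell and lymphoma lists lie right of 0 except Klf2, at -41.3.

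At promoter regions few changes passed. Of 14294, edgeR called 5 higher and 0 lower, with 1788 at an unadjusted p under 0.05, and limma called 5 higher and 1 lower. The 5 were Sec63 (chromosome 10, 42760496 to 42762496), part of protein import into the endoplasmic reticulum, from 42.7% ± 1.69 to 91.0% ± 4.33 (SD, n = 2), Mkrn1 from 26.5% ± 2.12 to 74.8% ± 3.07, Gpr146 from 38.9% ± 0.624 to 86.7% ± 3.77, H2-Oa, which modulates peptide loading in B cells, from 39.7% ± 8.44 to 87.2% ± 0.193, and Arhgef2 from 66.6% ± 11.6 to 95.2% ± 2.35, with edgeR adjusted p between 0.0235 and 0.0289. None of the 5 was called without any 1 of the 4 libraries, where 0 were higher. Relative to the genome-wide change 111 were higher and 1 lower. With at least 10 reads per CpG only 115 regions were tested, of which 0 were higher and 17 lower. With at least 1 read 21449 were tested, of which 116 were higher and 117 lower. The promoter regions of Myc (0% and 0.868%), Pax5 (5.56% and 5.98%) and Bcl6 (0% and 0%) had little methylation in Dfl and DKO, and Tet1 and Aicda differed by 0.421 and 0.471 points. The table gives no strand, so a region may be a gene's far end. At its other end H2-Oa was less methylated (27.3% in Dfl and 28.6% in DKO, edgeR adjusted p = 0.949), so its called region is doubtful as a promoter. The other ends of Sec63 (43.3% and 42.1%), Mkrn1 (87.1% and 76.3%) and Gpr146 (71.2% and 86.4%) did not pass the test either, and that of Arhgef2 was not measured. Camera called no list at promoter regions with CpGs of at least 5 reads, the lowest adjusted p being 0.578 (0.885 with an estimated correlation). With at least 1 read it called the lymphoma and developmental lists (adjusted p = 0.0189 each, or 0.684 with an estimated correlation). At promoter regions the B cell transcription factors had a median of 2.04 points and a mean log2 odds change of -0.12, progenitor genes a median of 1.41 and a mean of -0.258 points, and myeloid genes a median of 0.670 points with camera's direction down. No list member was called over all genes, and adjusted over the list alone 4 lymphoma genes, 1 T cell, 1 myeloid and 1 NK cell gene were higher, and 1 B cell transcription factor and 2 T cell genes lower.

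Few CpG clusters were called, and the median difference over those tested was 0 points. Of 16191, edgeR called 62 higher, with a median from 3.04% in Dfl to 24.1% in DKO, and 12 lower. The one in Cacna1e, chosen after its values were seen (chromosome 1, 154725482 to 154727125), went from 3.44% to 53.2% (edgeR adjusted p = 1.35e-14). Higher and lower calls numbered 1 and 0 without Dfl replicate 1, 1 and 0 without Dfl replicate 2, 104 and 10 without DKO replicate 1, and 115 and 34 without DKO replicate 2. Limma called 3 and 0, and relative to the genome-wide change 245 were higher and 7 lower.

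Of 688712 windows of 1 kb, edgeR called 2360 higher, with a median level of 27.3% in Dfl and 73.9% in DKO, and 2117 lower, with medians of 92.2% and 60.9%. The largest gain lay in Notch2, the receptor that directs marginal zone B cells (chromosome 3, 98025001 to 98026000), from 1.72% ± 2.44 to 88.1% ± 7.06 (SD, n = 2; 8 CpGs, 50 to 77 reads per library, edgeR adjusted p = 1.53e-06). A window in Tcf4, an E protein of B cells (chromosome 18, 69575001 to 69576000), went from 4.00% ± 5.66 to 81.6% ± 5.16. Others lay 9041 bp from Ccr6, a B cell chemokine receptor, 10117 bp from S100a10, 11047 bp from Alas1 and 183201 bp from Spdye4c, each gaining 77.3 to 79.2 points. The largest loss was in Fcmr, the IgM Fc receptor (chromosome 1, 130866001 to 130867000), from 85.6% ± 7.86 to 15.1% ± 5.10 (edgeR adjusted p = 6.17e-05), and windows in Ecd (-63.5 points), Cd200r3 (-62.5), Sgms2 (-57.8) and Pappa (-57.4) and 15681 bp from Vmn2r56 (-62.0) followed. Protein-coding gene bodies held 68.5% of higher windows (95% Wilson interval 66.6 to 70.3), 36.7% of lower ones (34.7 to 38.8) and 45.4% of those tested. Higher and lower calls numbered 300 and 60 without Dfl replicate 1, 453 and 58 without Dfl replicate 2, 19 and 3 without DKO replicate 1, and 205 and 16 without DKO replicate 2. Relative to the genome-wide change 5109 were higher and 577 lower.

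The Igh constant region, whose switch regions recombine during class switching, was tested on its own. The stretch ran between the outermost ends of the annotated constant genes (chromosome 12, 113256204 to 113422730). DNA between Ighm and the D segments, which start at 113430528, lay outside it. Switch regions were not located, so the windows do not show whether switch regions changed. Of 25 windows of 1 kb, edgeR called 0 over all windows, with 1 at an unadjusted p under 0.05, and limma called 0. Adjusted over the locus alone 1 window was lower, 113380001 to 113381000, from 99.1% ± 1.29 to 81.9% ± 5.40 (SD, n = 2; edgeR adjusted p = 0.0136). That call was absent without Dfl replicate 1, Dfl replicate 2 or DKO replicate 1, where 0 were called. Of 5 constant genes measured, 1 was lower adjusted over the list alone, Igha (chromosome 12, 113256204 to 113260236), from 84.5% ± 9.33 to 65.2% ± 11.9. Ighg2b differed by 11.9 points, Ighd by 3.16, Ighg3 by 2.22 and Ighm by -0.126. The list had a median of 2.22 points and a mean of -0.430, and camera did not call it (adjusted p = 0.187, or 0.535 with an estimated correlation). The other 3 constant genes had too few kept CpGs.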

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

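All tests of explanations in this part were chosen after the results were seen. Read coverage, which no comparison of methylation used, lay above the controls at chromosome 15 and at some immunoglobulin V segments. Chromosome 15 had 1.30 times the Dfl coverage in DKO replicate 2. The Igh V segments had 1.21 times in DKO replicate 1 but 0.932 times in DKO replicate 2, and the Igl V segments 1.04 times in DKO replicate 2 but 0.898 times in DKO replicate 1. The Igl value rests on 842 CpGs, where relative coverage was 1.23 against 1.21 and 1.16 in the Dfl libraries, so it is not shown to differ from the controls.

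In DKO replicate 2, chromosome 15 coverage was raised and Y coverage was 0.399 times Dfl. A coverage bias of that library is argued against by the lowest 2 Mb bin of chromosome 15, at 1.22, where 2 Mb bins of other autosomes had a 99th percentile of 1.03 and no other autosome as a whole exceeded 1.01. Female DNA mixed in would raise X, which was at 0.990. A cell population with an additional chromosome 15 and no Y may be present: the shares of cells were 59.2% (95% bootstrap interval 57.6 to 60.8) and 60.2% (59.2 to 61.1), a difference of -0.944 points (-2.86 to 0.931). Equal shares do not show that the same cells carry both changes, and the gain of 1 copy is assumed.

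Igk V coverage was 0.667 times Dfl in DKO replicate 1 and 0.513 times in DKO replicate 2. Mapping or library bias is argued against by 764 other stretches of that length, none of which fell below 0.923 in either library. More unrearranged cells in the Dfl sorts would make the Igh D segments lower in DKO too. In DKO replicate 1 these were at 1.09 times Dfl, above both Dfl libraries. If that library holds expanded clones, its D coverage also depends on the D segments those clones kept. Fewer unrearranged cells are therefore not excluded in DKO replicate 1. Few expanded clones may explain DKO replicate 1, where the Igk ratio to Dfl stepped by up to 0.309 between neighbouring 100 kb bins. The Igk ratio between the Dfl libraries stepped by up to 0.204. At the Igh V segments these steps were 0.362 and 0.157. In DKO replicate 2 the D segments were at 0.534 times Dfl, close to its Igk ratio, and the largest Igk step was 0.194. At the Igh V segments its largest step was 0.172, against 0.157 between the Dfl libraries. The chromosome 15 and Y values above would go with an expanded population in that library, but do not tie it to the Igk loss. Fewer unrearranged cells and expanded clones therefore cannot be told apart there.

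Methylation was lower across the genome in DKO. More complete conversion is argued against by lambda, where the mean of unconverted reads was 0.0138 points higher in DKO, with DKO replicate 1 below both Dfl libraries (0.222%) and DKO replicate 2 above (0.293%); mitochondrial C reads did go lower, from 0.868% and 0.893% in Dfl to 0.490% and 0.564% in DKO, but by far less than the genome-wide -4.59 points. Deeper sequencing is argued against by DKO replicate 2, which had a mean coverage of 7.49 against 7.73 in Dfl replicate 1 and was lower by -4.20 points. More cell divisions in DKO could leave gene-poor DNA less methylated, and gene-free windows differed from gene-rich ones by -9.24 points. Division was not measured. Genotype and the YFP sort separate the same libraries and cannot be told apart, nor can division if it differed between the groups. The coverage of Igk V, chromosome 15 and Y leaves open that the DKO libraries also differ from Dfl in cell make-up. Whether that lowers methylation was not tested. Levels are the sum of 2 marks, so loss of 5-hydroxymethylcytosine cannot be told from loss of 5-methylcytosine. Loss of Tet2 and Tet3 therefore stays open and untested as the direct cause.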

How the results depend on the processing

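The other end of each gene, chromosome 15 left out and all alternatives for genes with a higher 1 kb window were chosen after seeing the data; other alternatives were planned. Unless stated, the cause was not tested. A direction counted as reversed only for values called or given without a test.

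Genome-wide methylation stayed lower in DKO throughout, by -2.91 points with at least 10 reads, -4.22 with at least 1, -5.49 without the top coverage and -5.28 unweighted. With at least 10 reads, which kept 266848 CpGs, CpG clusters (-0.358), promoter regions (-2.03) and the densest CpGs (-0.192) reversed. Flanks were then at -4.05, gene bodies -5.80, intergenic CpGs -2.41, CpG densities 1 to 2, 3 to 5 and 6 to 10 at -9.77, -7.17 and -2.25, and X at -5.97. With at least 1 read, clusters were at 0.286, flanks -1.20, bodies -3.04, density 3 to 5 at -6.42 and 25 or more at 0.469. Without the top coverage these were clusters 1.13, flanks -1.61, intergenic -7.51, density 6 to 10 -3.01 and 25 or more 1.86. Windows at 40 to 60% reversed to 0.726 and 0.924 when classed by a single Dfl library. Tet3 segment coverage ranged from 3.28 to 4.31% of Dfl with a library left out.

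Promoter regions had 5 higher calls and 0 lower. Higher calls numbered 111 after centring, 8 on autosomes, 0 with at least 10 reads, 116 with at least 1, 9 without the top coverage, 8 without chromosome 15, 32 from 2 kb upstream, 29 at the other end and 0 to 0 with a library left out. Lower calls numbered 1 by limma, 1 after centring, 17 with at least 10 reads, 117 with at least 1, 3 from 2 kb upstream and 6 at the other end. Gene bodies gave 1104 higher and 171 lower after centring, 14 and 307 with at least 10 reads, 1243 and 3771 without a minimum, 55 and 67 at 20 points, and 180 to 417 higher with a library left out. CpG clusters gave 3 and 0 by limma, 245 and 7 after centring, 40 higher with more CpGs, 0 and 0 with at least 10 reads, 15 and 3 with at least 1, 98 higher without a minimum, 33 and 6 at 20 points, and 1 to 115 and 0 to 34 with a library left out.

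Windows of 1 kb gave 5109 and 577 after centring, 247 and 50 with more CpGs, 13 and 396 with at least 10 reads, 10612 and 24021 with at least 1, and 19 to 453 and 3 to 60 with a library left out. Windows of 500 bp gave 1367 and 313, and of 5 kb 6196 and 86727. Windows of 100 kb gave 5906 higher after centring, 725 and 3329 with more CpGs, 2 and 85 with at least 10 reads, and 836 to 1838 higher with a library left out. Fewer regions reach the minimum with more CpGs or reads, so these counts have unlike totals. With at least 10 reads, 115 promoter regions, 3106 gene bodies, 639 CpG clusters, 15819 windows of 1 kb and 108 of 100 kb were tested. With at least 1 read these totals were 21449, 19535, 31207, 1982851 and 25683. The Igh region had 2 windows called over all and 4 over the locus with at least 1 read, and 0 to 1 over the locus with a library left out.

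With the replicate block, promoter regions gave 129 higher and 62 lower, 1 kb windows 4506 and 8536, and Igh 1 window called over all. No pairing by replicate number was seen, since differences of the same number correlated at r = -0.00379 to 0.0254 across regions. Counting error in regions with few reads weakens such a correlation, so a shared effect is not excluded. The paired values are not preferred.

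Among list tests, the camera calls of B cell transcription factors and receptor genes ended with an estimated correlation (adjusted p = 0.440), and that of lymphoma genes did (0.507) as well as with at least 10 reads (0.0588). The estimated setting has few degrees of freedom with so few libraries, and fewer still with a library left out, so its losses decide little. With at least 1 read camera called lymphoma and developmental promoters (0.0189 each; 0.684 with an estimated correlation), and bodies of germinal centre (0.0348), DNA methylation enzyme (0.00983) and R-loop genes (0.0483; for these bodies 0.484 to 0.558 estimated). Without the top coverage it called these 3 and germline bodies (0.0446 each; 0.522 estimated). With a library left out, adjusted p ranged from 0.0155 to 0.182 for germinal centre, 0.0161 to 0.249 for R-loop, 0.00183 to 0.912 for T cell and 0.0478 to 0.123 for germline bodies, and no such call held with an estimated correlation. Fry calls ended with at least 10 reads or 1 read for B cell transcription factors (0.170, 0.0665) and germline bodies (0.266, 0.0765). With a library left out fry gave 0.0588 to 0.343 and 0.0484 to 0.343 for these, 0.0359 to 0.396 for DNA methylation enzyme bodies and 0.04998 to 0.9001 for DNA damage response promoters. For genes with a higher 1 kb window, the adjusted p of B cell transcription factors was 0.0690 with more CpGs and 0.00680 to 1 with a library left out. Receptor and lymphoma genes, on the threshold in the main setting, passed it by limma (0.0499 each), after centring and with the replicate block (0.00113 each) and with at least 1 read (0.00170 each), and receptor genes without the top coverage (0.0459). Lymphoma genes did not pass without the top coverage (0.141) or without chromosome 15 (0.406). Receptor genes did not pass without chromosome 15 (0.0561), and neither list did with more CpGs. Part of the small shifts near the threshold comes from the random draws. The Myc body reversed with at least 1 read (-0.612). Of 44 named regions called, 39 remained called by limma, 40 after centring and 33 with at least 1 read. At this depth and number of libraries, 58% of simulated 30-point changes were recovered at promoter regions and 31% at 1 kb windows. No other depth was simulated.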

Other observations

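The test of higher windows within gene lists was chosen after the data were examined. Of 20 B cell transcription factor genes, 11 held a 1 kb window that was higher in DKO: Bach2, Bcl11a, Ebf1, Foxo1, Ikzf1, Ikzf3, Irf8, Mef2c, Pou2f2, Runx1 and Spi1. Random lists of genes with like numbers of tested windows held 2.33 on average (10000 random lists, p = 0.0001, the smallest they can give, permutation adjusted p = 0.0034). The random lists were not matched on methylation level. Higher windows had medians of 27.3% and 26.3% in the Dfl libraries, against 87.5% and 87.8% for all tested windows. A list with more low windows in Dfl could therefore hold more higher ones. B cell receptor and surface genes held 5 against 1.08 (adjusted p = 0.0510) and lymphoma genes 6 against 1.71 (adjusted p = 0.0544), neither past the threshold. Both lie on it in this setting, since another draw of random lists gave an adjusted p of 0.0487 for each. Lymphoma genes did not pass without the top coverage (permutation adjusted p = 0.141) or without chromosome 15 (0.406). The transcription factors with a higher window numbered 5 without Dfl replicate 1, 5 without Dfl replicate 2 (permutation adjusted p = 0.0102 for each), 4 without DKO replicate 2 (0.00680) and 0 without DKO replicate 1 (1), where edgeR called 19 windows higher in the genome. With 1 library left out the receptor genes held 0 or 1 and the lymphoma genes 0 or 1.

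The genes with most higher windows, chosen after their values were seen, were Msi2 with 8 of 157 windows, and Cyth1, Foxn3 and Pip4k2a with 7 each. Another 8 genes held 6 each: Ankrd11, Arhgef3, Etv6, Foxp1, Mbnl2, Rabgap1l, Susd1 and Tcf4. Their order depends on the setting. Foxp1 held 19 against 16 for Msi2 after centring, and 34 against 23 with at least 1 read. With more CpGs per window only Msi2 kept any of its windows (2), and with at least 10 reads none of the 12 did. By edgeR these 12 genes held 0 lower windows. These counts rest on all 4 libraries: Msi2 held 3 without Dfl replicate 1, 5 without Dfl replicate 2, 0 without DKO replicate 1 and 3 without DKO replicate 2, and the other 11 genes held 0 to 3 in each of these.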
